A study of Amborella trichopoda with 4 samples.

How the data were processed

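Small RNA and degradome (PARE) libraries were made from leaf and from open female flowers of *Amborella trichopoda*. Per the labels, total RNA was extracted with a plant RNA reagent, small RNA libraries followed Illumina's preparation guide, degradome libraries followed a published PARE protocol, and sequencing was on an Illumina HiSeq. Each of the 4 deposited files lists tag sequences with their read counts, and the authors deposited these counts as whole numbers without normalization. Adapter trimming, length selection and any filter or alignment made before deposit are not given in the sources used here. The files themselves hold tags of 18 to 31 nt for small RNAs and of 18 to 20 nt for the degradomes, so longer and shorter inserts could not be counted. Groups came from the labels, with 1 library per tissue and assay and 2 libraries per assay.

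Total reads were 25781233 (flower) and 18092450 (leaf) for small RNAs, and 19990216 (leaf) and 12609502 (flower) for degradomes. Values are in RPM, reads per 1000000 of all reads in a file. A count of 0 allows up to 3 reads, which is 0.116 and 0.166 RPM in the small RNA libraries of flower and leaf, and 0.150 and 0.238 in the degradomes of leaf and flower. Shares carry 95% Clopper-Pearson intervals, counts 95% exact Poisson intervals, and ratios the exact conditional binomial interval.

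The families to count, the alternatives and the rules were chosen before the data were examined, except where stated. A list of 37 conserved mature sequences in 31 families, written from general knowledge, was matched to tags of 20 to 22 nt from their first base with at most 2 substitutions, and each tag went to its closest family. A family was called different between the libraries when it had at least 10 RPM in 1 of them and its whole 95% interval lay beyond 2-fold. The naming rule took every family at 10 RPM, with all past the 2-fold rule, the 5 most abundant 20 to 22 nt tags and the 5 most abundant 24-nt tags outside the families in each library, and at most 10 families with the most signature reads in each degradome. Tags named outside this rule are said to have been chosen after their values were seen.

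Alternatives for families were scaling by 20 to 24 nt reads, by 24-nt reads, by the median ratio of 12494 tags with at least 100 reads in both libraries, and by TMM (trims of 30% on ratios and 5% on means) over 63696 tags with at least 10 reads in both. Further alternatives were at most 0, 1 or 3 substitutions, and minimums of 0 or 100 RPM. Scaling by ribosomal RNA marker reads, of 18S and 5.8S together or of each alone, was added after the data were seen. Marker reads held a 12-base word of conserved 18S or 5.8S stretches in the sense direction. Size shares were also computed over distinct tags, without listed families and over 18 to 26 nt only. Shared tags were also counted after drawing the flower library down to the leaf depth and for tags of at least 2 reads.

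A signature read began with the exact reverse complement of bases 1 to 10 of a listed sequence, and each family was set against 100 shuffles that keep its base content but not the order of bases. Alternatives used 9 bases, distinct tags or the dominant tag of each family, and, added after the data were seen, 1 mismatch and scaling by reads outside the 100 most abundant tags. For tags with at least 5 reads over both degradomes, upstream bases were rebuilt from degradome tags that overlapped by at least 15 bases in steps of at most 4, taking the most abundant tag where several fitted. Pairing was scored with 1 per mismatch and 0.5 per G:U pair, doubled at miRNA positions 2 to 13, and a site needed a penalty of at most 4. The same steps were run on 20 shuffled sets. Rebuilding was chosen after the files were seen, because no reference genome was used here.

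Planned results that need a genome or transcripts were not run: targets with a degradome peak on transcripts, genes over 4-fold in the degradome with their gene lists, phased loci and genomic origin. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, with seed 1. The 2-fold rule, family assignment, the signature and site rebuilding were tested on simulated data, and the other steps were not. At levels of tags with at least 200 leaf reads, the 2-fold rule called 50 of 50 tags at each planted ratio of 0.2, 0.333, 3 and 5 and left all 800 with equal levels uncalled. Family assignment recovered 740 of 740 tags with 2 substitutions and took 0 of 100000 random tags. The signature step found 5 of 5 planted families and none of the 26 others, and rebuilding recovered 48 of 50 planted sites. Both of these tests used random bases. They lacked the base content and the very abundant tags of the data, and the planted sites were covered by evenly spaced tags, which real sites need not have.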

Results

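Small RNAs and the cut ends of messenger RNAs were profiled in leaf and in open female flowers of *Amborella trichopoda*, a shrub placed as sister to all other living flowering plants. The series held 4 libraries. Each tissue had 1 small RNA library and 1 degradome library, in which PARE (parallel analysis of RNA ends) captures the 5′ ends of uncapped, polyadenylated RNA fragments such as those left when a miRNA guides cleavage. The small RNA libraries held 25781233 reads in 4560684 distinct tags for the flower and 18092450 reads in 1765893 distinct tags for the leaf, all of 18 to 31 nt. The degradome libraries held 19990216 reads in 4305009 distinct tags for the leaf and 12609502 reads in 3992618 distinct tags for the flower, all of 18 to 20 nt. Each tissue and assay had 1 library and no replicate, so no test between tissues was made and every ratio compares libraries. The 95% intervals cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

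The first comparison asked how the size classes of small RNAs differed between the flower and the leaf library. The 24-nt class, the size of siRNAs that guide DNA methylation in plants, was the largest class in both libraries and took a larger share in the flower. It held 27.3% of flower reads (95% Clopper-Pearson interval 27.27 to 27.30%) and 14.3% of leaf reads (14.24 to 14.28%), a flower to leaf ratio of 1.91. The 21-nt class, the usual size of plant miRNAs, held 11.5% of flower reads and 13.5% of leaf reads, a ratio of 0.853. There were thus 2.38 reads of 24 nt for each read of 21 nt in the flower library and 1.06 in the leaf library. The 22-nt class held 8.16% of flower reads and 12.4% of leaf reads. The ends of the length range differed too. Reads of 18 nt took 4.29% in the flower and 8.86% in the leaf, and reads of 29 nt took 3.62% and 0.764%.

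The 24-nt class was also the most diverse. It made up 47.4% of the distinct tags of the flower library and 24.7% of those of the leaf library, with means of 3.25 and 5.91 reads per tag. Adenine was the first base of 48.6% of 24-nt flower reads and 35.4% of 24-nt leaf reads. Uracil (written T in the tags) began 43.0% of 21-nt flower reads and 35.1% of 21-nt leaf reads. Marker words of ribosomal RNA came from conserved stretches only, so reads with them are not the full load of either RNA. Reads that carried such words went opposite ways for 18S and 5.8S. Those of 18S were at 4067 RPM (reads per 1000000 reads of a library) in the flower and 5207 in the leaf, a ratio of 0.781 (95% interval 0.774 to 0.788). Those of 5.8S were at 28061 and 18507 RPM, a ratio of 1.52 (1.51 to 1.52). In the degradomes the values were 750 in the flower and 1531 in the leaf for 18S, and 75.6 and 68.6 for 5.8S, a ratio of 1.10 (1.01 to 1.20).

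**Figure D1:**
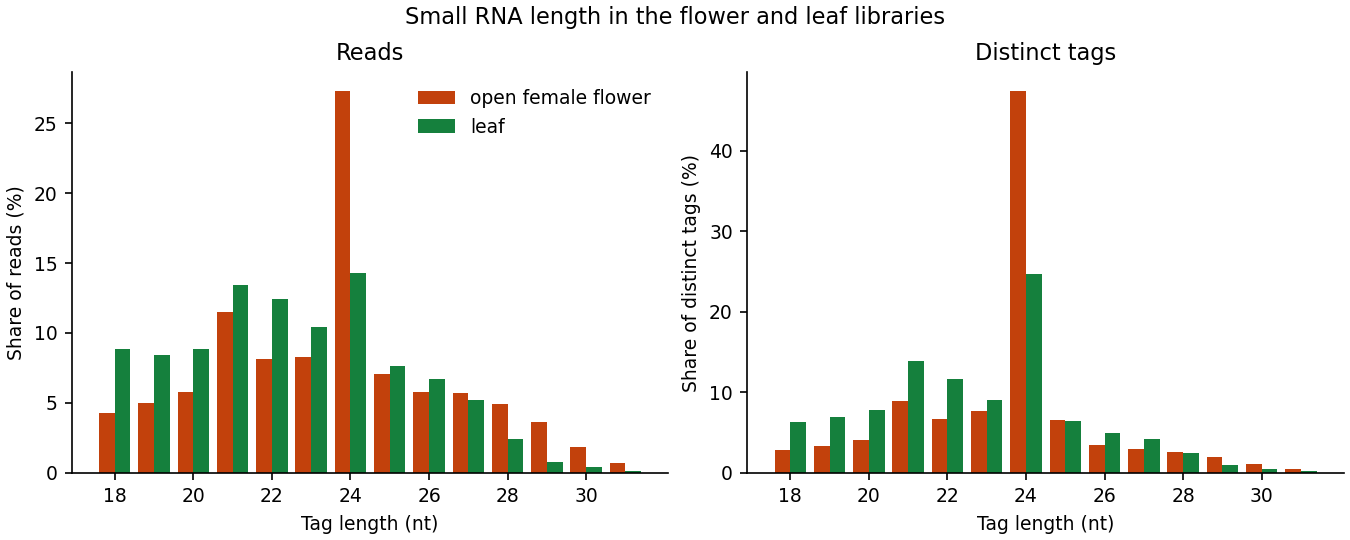
Share of reads (left, %) and of distinct tags (right, %) against tag length (nt) in the flower (orange) and leaf (green) small RNA libraries, 1 library each. The 24-nt bar reaches 27.3% of reads and 47.4% of distinct tags in the flower library, against 14.3% and 24.7% in the leaf library.

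Overlap between the libraries differed by size class. Of the 408790 distinct 21-nt tags of the flower, 13.6% (95% interval 13.5 to 13.7%) also occurred in the leaf, and 22.7% of the 245171 leaf tags occurred in the flower. At 24 nt, 6.34% of the 2162143 flower tags (6.30 to 6.37%) occurred in the leaf and 31.4% of the 436526 leaf tags occurred in the flower. Shared tags were the abundant ones, since they carried 82.6% of 21-nt and 51.7% of 24-nt flower reads. These shares depend on depth and on tags read once, which made up 71.5% of all distinct flower tags and 56.6% of leaf tags. With tags of at least 2 reads in both libraries, the shared parts of the 21-nt classes were 25.6% for the flower and 26.8% for the leaf.

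The next comparison asked which conserved miRNA families were more abundant in the reads of one tissue. Of 31 listed families, which include the trans-acting siRNA tasiARF, 30 had at least 1 read in the flower library and 28 in the leaf library. No read within 2 substitutions of the listed miR403 sequence was found in either, which allows up to 0.116 RPM in the flower and 0.166 in the leaf. Family reads made up 1.28% of all reads in the flower and 1.04% in the leaf. These shares leave out forms that start before the listed base, which for miR166 alone were at 7552 RPM in the flower and 2000 in the leaf. The families miR166 and miR159 together gave 82.3% of family reads in the flower, and miR396, miR166 and miR159 gave 88.3% in the leaf. At 10 RPM or more in 1 library, 17 families could be compared. The 2-fold rule, by which the whole 95% interval of the ratio had to lie beyond 2-fold, was met by 6 families with higher and 5 with lower RPM in the flower library.

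With at most 2 substitutions, the families higher in the flower library were led by miR171. It is known in other plants to target GRAS transcription factors that maintain meristems. It stood at 98.4 RPM in the flower and 1.60 in the leaf, a 61.4-fold difference (95% interval 42.6 to 91.8). Counts of miR390, which triggers the making of trans-acting siRNAs, were at 26.1 against 0.553 RPM, 47.3-fold higher (25.6 to 99.1). For miR394, known to act on an F-box gene in shoot meristems, the values were 50.7 and 2.32, 21.9-fold higher (16.1 to 30.5). The miR319 family, which targets TCP genes of leaf and petal growth, was at 781 and 74.3, 10.5-fold higher (9.94 to 11.1). The juvenile-phase regulator miR156 was at 97.8 and 25.8, 3.80-fold higher (3.44 to 4.20). The most abundant family of the flower library was miR166, a regulator of HD-ZIP III genes and organ polarity. It was at 7852 and 3264 RPM, 2.41-fold higher (2.38 to 2.43).

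Among the families lower in the flower library, miR396, which targets growth-regulating factors, was the most abundant counted family of the leaf, ahead of miR166 only because forms of miR166 that start before the listed base were left out. It stood at 3507 RPM in the leaf and 519 in the flower, 6.75-fold higher in the leaf (95% interval 6.63 to 6.88). The sulfate-starvation miRNA miR395 was at 17.4 against 0.233 RPM. Its leaf to flower ratio of 74.6 (33.9 to 205) rested on 6 flower reads. Reads of miR397, known to target laccases, were at 193 in the leaf and 9.93 in the flower, 19.4-fold higher in the leaf (17.1 to 22.1). For miR393, a regulator of auxin receptors, the values were 26.1 and 2.56, 10.2-fold higher in the leaf (7.88 to 13.4). For miR164, a regulator of NAC genes at organ boundaries, they were 63.0 and 25.8, 2.44-fold higher in the leaf (2.22 to 2.69).

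The other 6 families at that level did not meet the rule. Their flower to leaf ratios were 1.25 for miR535, 1.12 for miR159, 1.03 for miR2950, 0.801 for miR167, 0.797 for miR398 and 0.695 for miR168, and the first 5 of these fell on either side of 1 depending on the scaling. The miR398 value leaves out a 21-nt tag of the same kind. TGTGTTCCCAGGTCGCCCCTG lay 3 substitutions from the listed sequence and differed from the dominant counted miR398 tag, TGTGTTCTCAGGTCGCCCCTG, by T8C, counted from 1 at the 5′ end of the latter. It was chosen after its values were seen. It had 905 RPM in the leaf and 28.9 in the flower, 31.3-fold higher in the leaf (95% interval 29.1 to 33.7).

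Other scalings multiplied every flower to leaf ratio by a common factor, from 0.523 (24-nt reads) to 1.29 (median of ratios). None of the called families crossed a ratio of 1 under the 8 scalings, but scaling by 24-nt reads moved the split from 6 higher and 5 lower to 4 higher and 8 lower, with miR156 at 1.98 and miR166 at 1.26. The call for miR166 also ended under scaling by ribosomal marker reads, pooled or of 5.8S alone, and that for miR164 under median of ratios, TMM and 18S marker reads. The miR171 call rested on the tag TGATTGAGCCGCGCCAATATC (2101 flower reads, 11 leaf reads), 1 substitution from a list that was written from general knowledge. The ratio was 1.68 over exact listed sequences alone, which leave this tag out, and 24.3 with up to 3 substitutions. In both of these counts miR390 stood above miR171, at 49.1 and 47.3. Exact sequences alone also ended the call for miR397, a family whose dominant tags had 1 substitution and differed between the libraries (TCATTGAGTGCAGCGTTGGTG in the flower, TCCTTGAGTGCAGCGTTGATG in the leaf). For miR167, whose dominant tag also has 1 substitution, the ratio over exact sequences was 2.74.

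**Figure D2:**
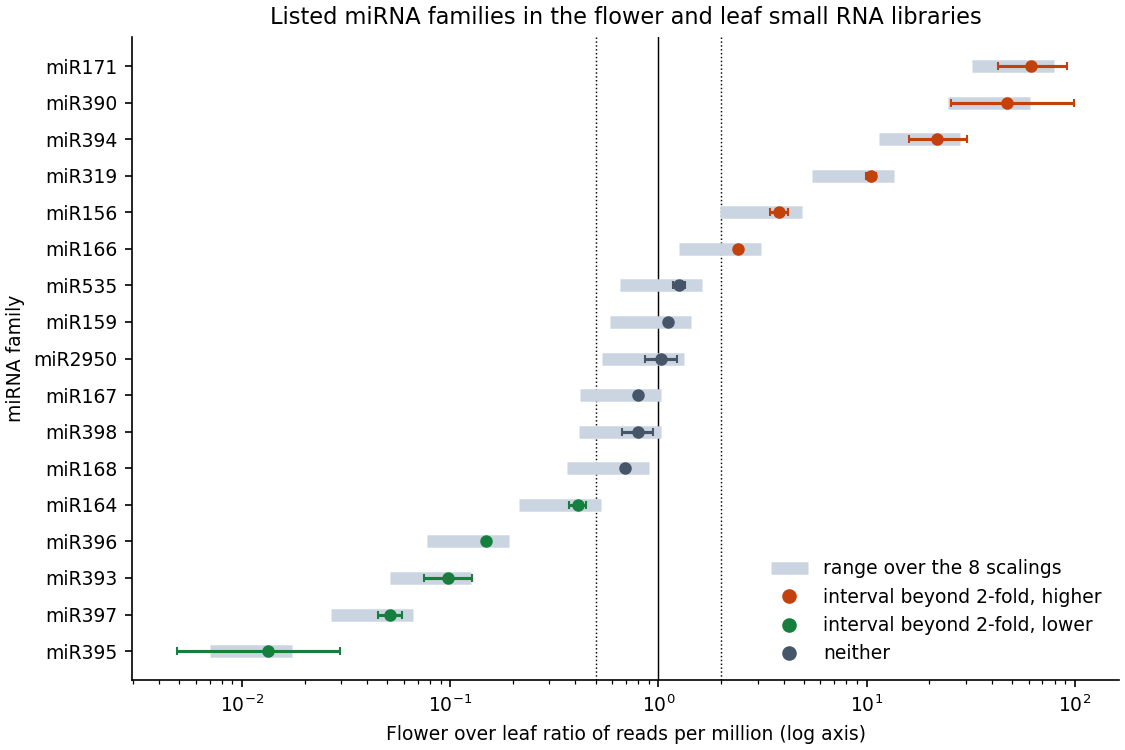
Flower over leaf ratio of RPM (log axis) for the 17 miRNA families with at least 10 RPM in 1 small RNA library. Points are ratios with 95% counting intervals, grey bars span the 8 scalings, the solid line marks equal values and the dotted lines mark 2-fold; ratios run from 61.4 for miR171 down to 0.0134 for miR395.

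Outside the counted families, the most abundant 20 to 22 nt tag of the flower library was TCTCGGACCAGGCTTCATTCC, a form of miR166 that starts 2 bases before the listed sequence. It had 7503 RPM in the flower and 1979 in the leaf, a ratio of 3.79 (95% interval 3.75 to 3.83). The next were CGCGAGAAGTCCACTGAACCT at 4230 and 2633 RPM, its 22-nt form TCGCGAGAAGTCCACTGAACCT at 2421 and 1880, and CCTGTGTCGCAACGATTCGT at 3611 and 1713. The tag AGTTACTAATTCATGATCTGGC was the fifth in the flower at 2369 RPM and the most abundant in the leaf at 14983, 6.32-fold higher there. In the leaf it was followed by a nested set, AACCGTAGTAATTCTAGAGC at 3752 RPM, ATAACCGTAGTAATTCTAGAGC at 3337 and TAACCGTAGTAATTCTAGAGC at 3316, with 1707, 2049 and 1625 in the flower. The leaf tag CTTGTGTCGCAACGATTCGT had 3723 RPM there and 2.37 in the flower.

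The most abundant 24-nt tags of the flower were AGGCCCGAGAGCTCTTGAATCACT, 5.20-fold higher than in the leaf, CAGCCCTGTGTCGCAACGATTCGT, 4.40-fold higher, and TTGGACCAGACTGGCCAAGGCACT, 7.49-fold higher (95% interval 7.20 to 7.80). Near-equal values were found for TTTGAACGCAAGTTGCGCCCGAGG, which holds a word of 5.8S ribosomal RNA (ratio 1.01), and CGCACCACGAGGCGCTGTCGGCGA (1.15). In the leaf the leading 24-nt tags were ATAACCGTAGTAATTCTAGAGCTA, 1.74-fold higher than in the flower, CAGCCCCGCGTCGCACGGATTCGT, 8.43-fold higher, CCTAACAGACCGAGAGATTTGAAC, 1.60-fold higher, TAACCGTAGTAATTCTAGAGCTAA, 2.70-fold higher, and ATTCAAATGAGAACTTTGAAGGCC, 3.36-fold higher. Among the abundant tags listed here and in the paragraph before, no other held a ribosomal marker word. Those words came from conserved stretches only, so the lack of one does not exclude a ribosomal origin. No genome was used, and the origin of these tags was not analysed further here.

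The degradome comparison asked for which miRNA families cut target ends could be seen in each tissue. Slicing opposite miRNA positions 10 and 11 leaves a fragment whose first 10 bases pair with miRNA bases 1 to 10, and reads with such a start are called signature reads here. Signature reads were most numerous for miR393 in both libraries, with 5309 reads (266 RPM, 95% exact Poisson interval 258 to 273) in the leaf and 858 (68.0 RPM, 63.6 to 72.8) in the flower. They were also frequent for miR160, a regulator of auxin response factors, with 3915 reads in the leaf and 192 in the flower, and for miR156, with 1138 and 218. For miR171 there were 436 in the leaf and 52 in the flower.

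In the leaf degradome, 7 families (miR156, miR160, miR169, miR171, miR393, miR396 and miR529) had more signature reads than each of 100 shuffles of their sequences. In the flower degradome, 6 did (miR156, miR160, miR164, miR393, miR396 and miR529). Chance alone would give 0.307 of 31 families at this level, were listed and shuffled starts equally common by chance. The shuffles do not keep the order of bases, so this rate is approximate. Over all families the leaf held 11531 signature reads against a shuffle median of 295, a ratio of 39.1, and the flower 1972 against 284.5, a ratio of 6.93. No shuffle reached either of these totals, while with 1 mismatch allowed 1 leaf and 2 flower shuffles did, as did 2 flower shuffles for dominant tags. By reads, the families miR390, with 62 and 46 reads, miR2950, with 42 in each, and tasiARF, with 42 and 39, stayed within their shuffles. Signatures were sought from the listed start only. Reads of miR390 and tasiARF that start earlier outnumbered those at the listed start in both small RNA libraries, and their cuts would be missed. With each distinct tag counted once, miR2950 was above all shuffles in both libraries and miR390 in the flower, while miR169 and miR171 in the leaf and miR160 and miR164 in the flower were not. In the leaf, 1 tag gave 91.0% of miR393 and 92.4% of miR160 reads, and over distinct tags the ratios to the shuffle median were 2.93 in the leaf and 2.39 in the flower. For miR529 the leaf count of 112 lay just above the highest shuffle of 107 and was spread over 78 distinct tags. With 9 bases the miR529 call ended in both libraries and that for miR171 in the leaf. In the leaf, 9 bases raised miR166 from 4 to 406 reads (highest shuffle 232) and miR319 from 6 to 250 (highest shuffle 147). In the flower both stayed within their shuffles.

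**Figure D3:**
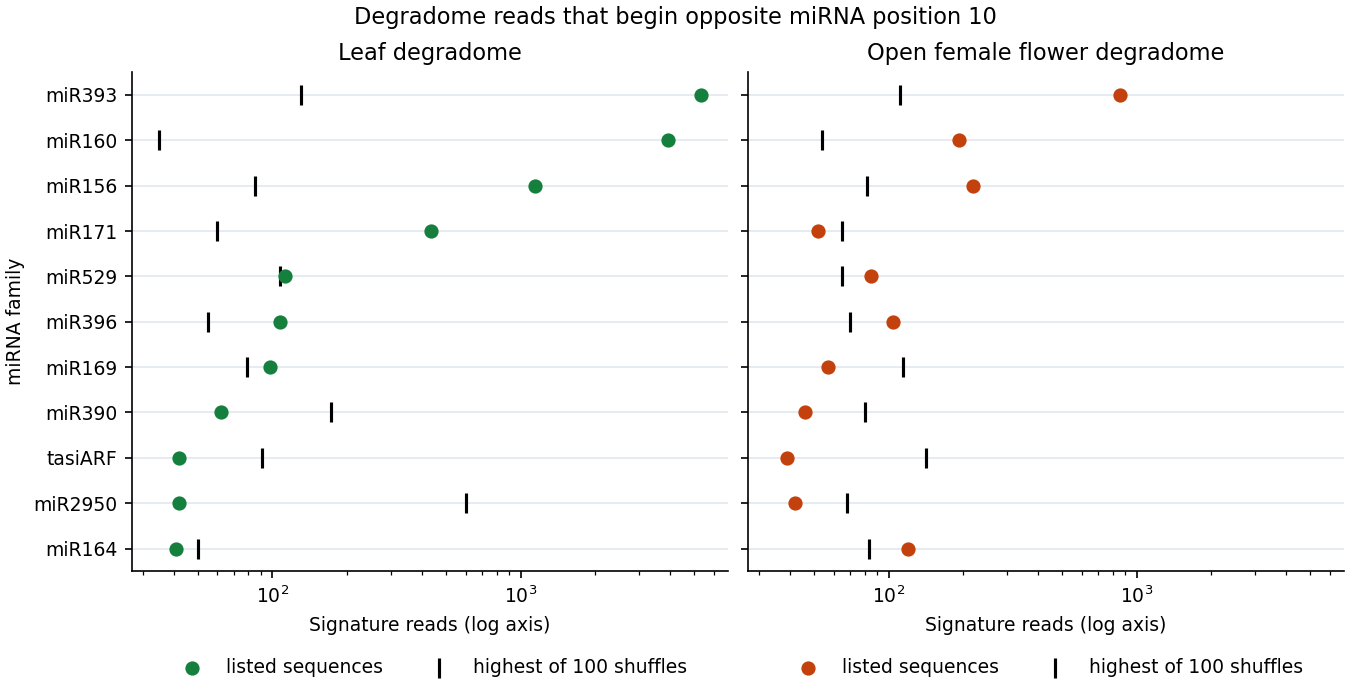
Degradome reads whose first 10 bases pair with miRNA bases 1 to 10 (log axis, reads) for the families with most such reads in the leaf (left) and flower (right) libraries, 1 library each. Dots are listed sequences and black ticks the highest of 100 shuffles; miR393 stands at 5309 against 130 in the leaf and at 858 against 111 in the flower.

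Overlapping degradome tags allowed the bases upstream of some signature tags to be rebuilt, so that pairing with the rest of the miRNA could be scored. Upstream bases were rebuilt for 49 of the 86 tags with at least 5 reads, which held 7855 of their 12670 reads, and only these were scored. Sites with a penalty of at most 4 were found for miR393, miR156 and miR171 and accounted for 52.5% of the 12670 signature reads. The highest value among 20 sets of shuffled sequences was 9.60%, and 2 of the 20 sets had any such read. A single miR393 tag gave 5205 of the 6649 reads with a site, and without it the share was 19.3%. By tags, 16 of 86 had a site (18.6%), against 2 of 13 (15.4%) in the highest shuffled set and 3 of 393 over all sets. Of rebuilt tags alone, 16 of 49 had a site, against 2 of 12 in that shuffled set. The 16 include 19-nt forms and 1-base variants of the same fragment, so they are not separate cuts. The miR393 site was GAAACAATGCGATCCCTTTGGA (penalty 2), the miR171 site GATATTGGCGCGGCTCAATCA (penalty 1) and the leading miR156 site GTGCTCTCTCTCTTCTGTCA (penalty 1). For the leading miR160 tag, GAGCCAGGCATGGCCGTTTC, with 3616 leaf reads, the upstream bases could not be rebuilt, so its pairing with miR160 was not scored. Genes and positions of the sites were not analysed here.

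Along the rebuilt stretch around the miR393 site, 96.8% of leaf reads (95% interval 96.3 to 97.3%, 4835 of 4993) and 86.1% of flower reads (82.5 to 89.3%, 373 of 433) began at the predicted cleavage position. At the miR156 site it was 90.04% of leaf reads (660 of 733) and 53.4% of flower reads (39 of 73). A further 23 flower reads began 1 base downstream, the predicted cleavage position for another listed miR156 sequence, and both positions together held 84.9% of flower reads (62 of 73) and 91.95% of leaf reads (674 of 733). The miR171 site had 58.7% of leaf reads (359 of 612) and 49.3% of flower reads (37 of 75) at that position. A further 223 leaf reads and 32 flower reads began 3 bases upstream of it.

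**Figure D4:**
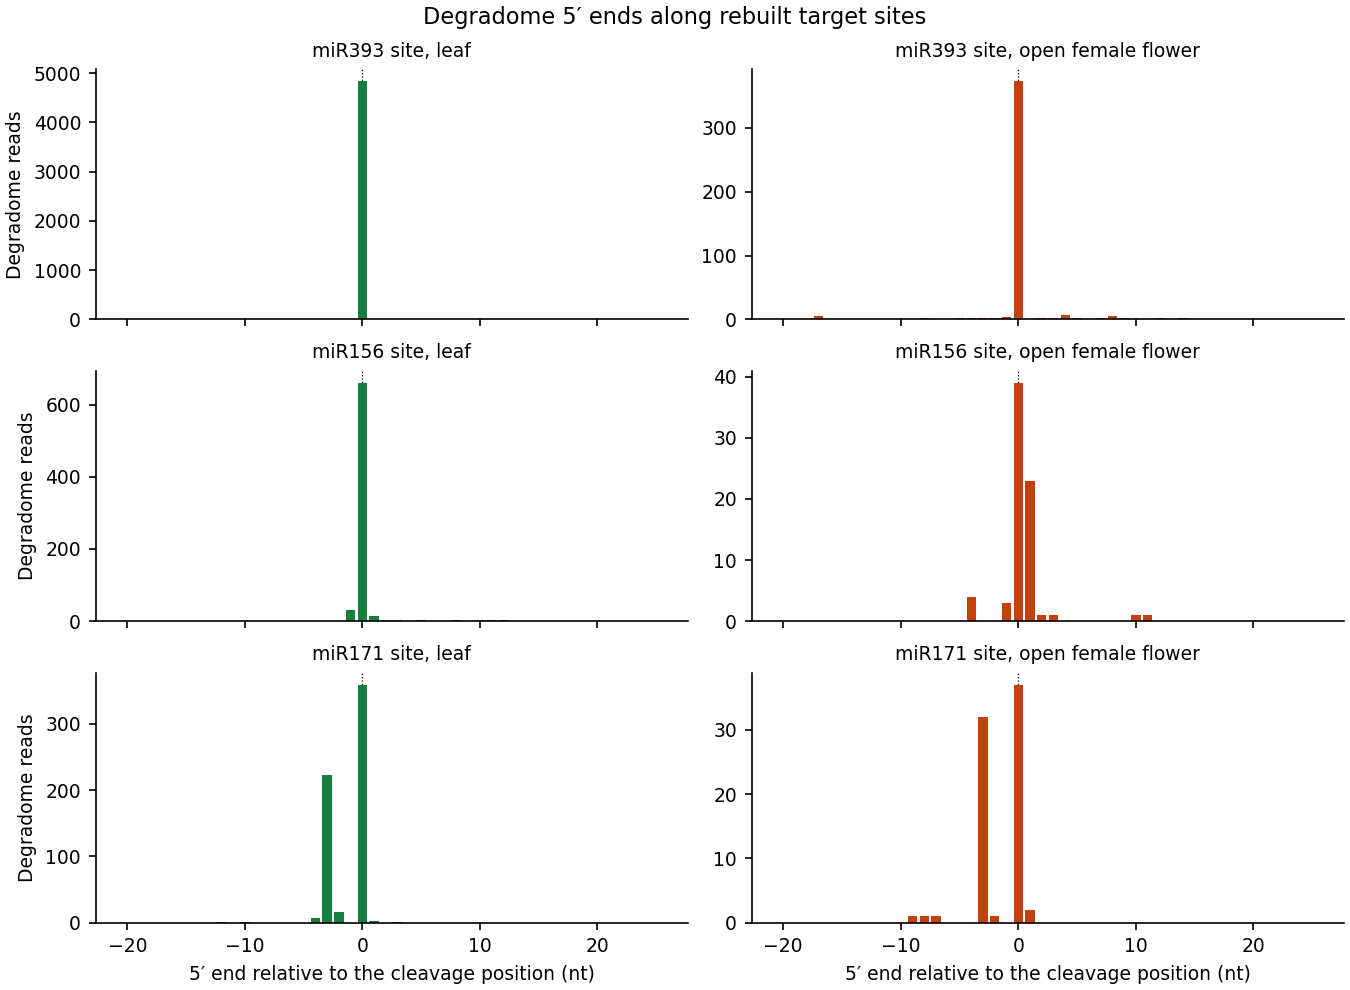
Degradome reads by 5′ end position (nt, 0 is the predicted cleavage position) along rebuilt miR393, miR156 and miR171 sites in the leaf (left) and flower (right) libraries, with a separate read axis in each panel. The miR393 site has 4835 leaf reads at 0, and the miR171 site has 359 leaf reads at 0 and 223 at the position 3 bases upstream.

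The RPM of signature reads and of miRNA reads were then compared family by family, for the 8 families above all shuffles in at least 1 degradome. Signature reads were higher in the leaf degradome by 12.9-fold for miR160 (95% interval 11.1 to 14.9), 5.29-fold for miR171 (3.96 to 7.19), 3.90-fold for miR393 (3.63 to 4.20) and 3.29-fold for miR156 (2.85 to 3.82). They were higher in the flower degradome for miR164, 4.64-fold, and for miR396, 1.54-fold (1.16 to 2.04), the latter with an interval that took in 1 when scaled by reads outside the 100 most abundant tags (1.10). With 9 bases the values were 2.90-fold for miR164 and 2.59-fold for miR396, and 1.85-fold (1.62 to 2.13) for miR396 under that scaling. Signature and miRNA reads went in opposite directions for miR156, miR164 and miR171 under each scaling tried, and in the same direction for miR393. The flower value of miR171 (52 reads, highest shuffle 65) and the leaf value of miR164 (41 reads, with 2 shuffles as large) lay within their shuffles. Of the 120 flower reads of miR164, 61 (50.8%) were of 1 tag, which was not the leading miR164 tag of the leaf. For miR160, miR169, miR396 and miR529 at least 1 of the directions was open or changed with the scaling. The 8 families were picked for their signature counts, and with 1 library per tissue these directions are those of the libraries.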

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

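The tests on breakdown tags, on chance in families without a rebuilt site, on a single scaling factor and on 24 nt against neighbouring lengths, together with scaling by ribosomal marker reads, were chosen after the result was seen.

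A signal outside the counted families came from the tag that starts 2 bases before the listed miR166 sequence, at 7503 RPM in the flower library. Among 31-nt flower reads, a length no comparison used, 41.9% began with G, against 21.96% in the leaf, but a single tag with 26.2% of these reads carries the excess, since without it the shares were 21.3% and 21.9%. The most abundant degradome tag, TGCATTGGATGGATGCCCGG, took 9.01% of leaf and 14.3% of flower degradome reads, and it pairs with no listed family at its start.

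The first pattern weighed is the excess of signature reads over shuffled sequences. If a few very abundant breakdown tags caused it, counting each distinct tag once would leave about the number chance gives. At least 4 of the families above all 100 shuffles by reads stayed so in each library. This cannot rule such tags out where 1 tag leads a family, because near copies of it count as distinct tags. The leading miR393 tag (5205 reads) came with 1-base variants of 53 and 8 reads. The 2 families that did not stay above in each library (miR169 and miR171 in the leaf, miR160 and miR164 in the flower) leave such tags open too, because 1 target cut at 1 position gives the same. Chance matches of 10 bases would not pair upstream. Yet 52.5% of signature reads in tags with at least 5 reads (19.3% without the leading miR393 tag) had a rebuilt site, against at most 9.60% in 20 shuffled sets. By tags, though, it was 18.6% against at most 15.4%, the latter 2 of 13. Tags that could not be rebuilt count as without a site in these shares, and for the listed sequences 49 of 86 tags were rebuilt. Among families without a rebuilt site, chance at the rate of these shuffles, which do not keep base order, would leave at most 1 above all of them. In each library 4 were above, with miR160 at 3915 leaf reads against at most 35, so chance at that rate is not the whole cause there. Chance stays open for miR164, miR169, miR396 and miR529 one by one. Cleavage guided by the miRNA may explain the excess for miR393 and miR156, as a hypothesis found and tested on the same libraries, though dominant tags alone lost miR156 in the leaf and miR393 in the flower, and 1 mismatch lost miR393 in both and miR156 in the flower.

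The second pattern is that families differed by more than 2-fold in both directions. If a scaling factor were the whole cause, a better one would leave 1 direction, but at least 4 families stayed past 2-fold in each direction under every scaling tried. This count could not have come out otherwise, because the scalings multiplied all ratios by 0.523 to 1.29 while the ratios ran from 0.0134 to 61.4. What holds is narrower: a common factor moves all families alike and leaves the spread between them as it is. Different size selection would give families one common ratio among 21-nt tags, and the log2 ratios over 21-nt tags alone spanned 12.20. Unequal RNA breakdown stays open, because it may act unevenly on families, which division by ribosomal marker reads, 1 factor for all, cannot undo (5 families stayed on each side). A tissue difference stays open too, untested, since with 1 library per tissue the plant, growth condition and library preparation may differ along with it.

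The third pattern is the larger 24-nt share of the flower library. Unequal breakdown that acts evenly over lengths would leave the 24-nt excess over neighbouring lengths, per 21-nt excess, alike in the libraries. This excess was 2.36 times as large in the flower. Breakdown that favours some lengths stays open, because the excess cannot tell it apart. A cut by size would move 23 and 25 nt along, but the 24-nt ratio was at least 2.07 times theirs (0.791 and 0.924). The libraries did differ in length over the wider range, with 4.29% of flower and 8.86% of leaf reads at 18 nt and 3.62% and 0.764% at 29 nt. Unequal size selection over that range thus stays open and may bear on 24 nt against 21 nt. A few abundant tags are not the whole cause, since 24-nt tags with 1 to 5 reads took 11.2% of flower and 3.67% of leaf reads, 3.06 times the leaf share. All 24-nt reads took 27.3% and 14.3%, so tags with more than 5 reads also hold part of the difference. Deeper sequencing does not change a share of reads in expectation, so thinning could bear on distinct tags only. After drawing the flower library down to the leaf depth, its 24-nt share of distinct tags was still 1.92 times that of the leaf. More varied 24-nt siRNAs in the flower may explain the pattern, as a hypothesis, but whether these tags are siRNAs was not tested. Other differences in library preparation stay open because each tissue had 1 library.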

How the results depend on the processing

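Scaling by ribosomal marker reads, the 1-mismatch signature and degradome scaling outside the 100 most abundant tags were chosen after the data were seen. No called value changed direction. The cause of each shift given here was not tested unless it follows from the alternative's construction. Counted over distinct tags, without listed families and within 18 to 26 nt, the 24-nt share was 47.4%, 27.6% and 32.8% in the flower and 24.7%, 14.4% and 15.7% in the leaf, and the 21-nt share was 8.96%, 10.4% and 13.8% in the flower and 13.9%, 12.6% and 14.8% in the leaf. The flower had the higher 24-nt and the lower 21-nt share each time. Thinning the flower library gave shared 21-nt tags of 15.6% (flower) and 19.97% (leaf) and shared 24-nt tags of 7.38% and 28.3%. Requiring 2 reads gave 25.6%, 26.8%, 10.2% and 35.1%. Scaling by 24-nt reads gave 8 families lower instead of 5, adding miR167, miR168 and miR398. A minimum of 100 RPM left 2 higher instead of 6 and 2 lower instead of 5, because fewer families were compared. Without a minimum there were 8 higher, adding miR477 and tasiARF, and 5 lower. Of the ratios of the 17 families over the alternatives, 141 kept call and side of 1, 8 lost the call (miR156, miR164, miR166 or miR171) and 5 gained one. The other 14, of uncalled families, crossed 1: miR167 went from 0.801 to 2.74 with exact sequences, and scaling moved miR159, miR167, miR398, miR535 and miR2950. Exact sequences alone also ended the miR397 call, and 3 substitutions added miR398 at 0.0447. At most 1 substitution moved miR398 from 0.797 to 0.100 without a call, because its dominant tag has 2 substitutions. In the leaf, signature reads over the shuffle median were 39.1 as reported, 11.1 with 9 bases, 2.93 with distinct tags and 2.47 with 1 mismatch. In the flower they were 6.93, 2.98, 2.39 and 1.44. In the leaf, families above all shuffles fell from 7 to 4 with dominant tags (miR156, miR169 and miR396 lost) or with 1 mismatch (miR169, miR171 and miR393 lost), and 9 bases kept 4 of the 7 (miR169, miR171 and miR529 lost, miR166 and miR319 gained). In the flower they fell from 6 to 4 with 9 bases (miR164 and miR529 lost) or dominant tags (miR160 and miR393 lost), and to 2 with 1 mismatch (miR156, miR160, miR164 and miR393 lost). With 1 mismatch 1 leaf and 2 flower shuffles reached the total. For dominant tags 2 flower shuffles did. Scaling outside the 100 most abundant tags changed the side of the interval for miR169 (0.660) and miR396 (1.10), and of none of the other 6 families. The 12-base signature with 1 mismatch was not run, because only 10 bases of a fragment pair with the miRNA. Alternatives for transcript targets, degradome genes, phased loci and genomic origin were not run for want of a genome. No paired analysis was possible because each tissue and assay had 1 library. Depth limits miR395, with 6 flower reads, and miR390, with 10 leaf reads.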

Other observations

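The tags in this part were picked after their values were seen, and no test was planned for them. Forms of miR390 and tasiARF that start before the listed sequence were also more abundant in the flower library. The miR390 form TAAAGCTCAGGAGGGATAGCG, which starts 2 bases early, had 812 flower reads and 22 leaf reads, a ratio of 25.9 (95% interval 17.0 to 41.6), and outnumbered the 674 flower and 10 leaf reads counted for the family. The tasiARF form TTTTCTTGACCTTGTAAGACC, also 2 bases early, had 192 flower reads and 4 leaf reads, 33.7-fold higher in the flower (12.9 to 125). In the flower library 317 reads of tasiARF started early and 35 at the listed base. The miR319 form CTTGGACTGAAGGGAGCTCCC, 1 base early, had 4060 and 310 reads, 9.19-fold higher in the flower (8.19 to 10.3). Early forms of miR156 went against their family count on few reads, with 41 in the flower (1.59 RPM) and 66 in the leaf (3.65 RPM).

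The position 3 bases upstream of the miR171 cleavage position held 36.4% of leaf and 42.7% of flower degradome reads along that site. The fragment that begins there pairs in its first 10 bases with a 20-nt tag, TTGAGCCGCGTCAATATCTC, which lay 3 substitutions from a listed miR171 sequence and was left out of the family count. That tag had 1622 flower reads and 96 leaf reads, 11.9-fold higher in the flower (9.65 to 14.7).

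The tag CTTGTGTCGCAACGATTCGT differs from CCTGTGTCGCAACGATTCGT by C2T, counted from 1 at the 5′ end of the latter. It made up 68.5% of the reads of the pair in the leaf (67362 reads against 30999) and 0.0655% in the flower (61 against 93094). Among 31-nt flower reads, 1 tag (49105 reads) made up 26.2%, and it had 12 reads in the leaf library.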
